A study of Mus musculus with 6 samples.

How the data were processed

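Bulk RNA sequencing was deposited for 6 libraries from adult B6D2F2 mice, CRISPR-edited per the labels, in which KRAS was read out as a fusion with the yellow fluorescent protein Citrine. Per the labels' protocols, the pancreas was digested, acinar cells were sorted by flow cytometry on the Citrine-KRAS signal, RNA was extracted with a column kit, and libraries were made with the NEBNext Ultra RNA kit. There were 3 libraries of KRAS-positive cells and 3 of KRAS-negative or low cells, called KRAS-negative/low here. Whether a kit setting that marks strand was used is not given in the sources used here, so antisense partners cannot be told apart. Labels give no sorting gate other than the Citrine-KRAS level and the words acinar cells. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

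The deposited table gave FPKM (fragments per kilobase and library total) for 53801 genes by Ensembl identifier, per the labels. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the mm10 build, with no version or role; the annotation and the normalization of the FPKM are not given in the sources used here. In each group 1 column was headed 1557 while the remaining title carried 1577. These columns were used as replicates of their group without a number and are called the unnumbered libraries. The other columns matched the titles 1551 and 1659.

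The deposited FPKM could not be read as they stood. Of 322806 cells, 204546 were 0 and 58459 were below 1 and readable. The other 59801 cells had lost their decimal mark, so their digits were known but not their power of 10. The mark was recovered from whole reads. An FPKM times the gene's length times the library size must be a whole number of reads, which left a few possible powers of 10 per cell. Lengths were exon unions of GENCODE M21 (build GRCm38), and the library sizes were fitted to the values themselves. Of the readable values, 94.7% to 96.1% per library came within 0.001 of a whole number of reads at the annotated length. Of the cells with a lost mark, 91.7% to 92.2% had a whole-read reading at the annotated length. For 1003 genes the length was inferred from the cells themselves, among candidates from 20 to 30000 bases, and 94.4% of these genes lay on chromosomes 16 to 19. The powers of 10 of a gene were then weighed together. A count was given a prior inversely proportional to its size. In a first pass the likelihood came from the spread between replicates of the same group and a broad term for the group difference. In a second pass it came from the 8 nearest profiles of genes already resolved. The group labels thus entered the recovery, which favours readings that make replicates of a group agree. For genes with a lost mark the spread within groups may be understated and p-values may be too small. No alternative left the group labels out of the recovery. A gene entered the tests when the posterior probability of its reading was at least 0.95, which held for 12523 of 13095 genes with a lost mark (95.6%). The posteriors imply 38.2 wrong genes among these. Another 572 genes stayed below that limit, and 555 of them had a mean FPKM of at least 1 and were left out of the tests. Several abundant genes with large group differences are among them, such as Try5, Amy2a5 and Ptf1a, and values of such genes are given only as their most probable reading.

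The recovery was adjusted against internal checks before any group test was run. Among recovered values of at least 10, 9.61% took a reading above the smallest that gave whole reads, meaning a read count ending in 0, and 0.927% of those of at least 100 took a reading at least 100 times the smallest. Library sizes predicted from the recovered reads by the median ratio between libraries lay within 0.685% of the fitted sizes. In data simulated for this comparison with known decimal marks, 12288 of 13329 genes with a lost mark were resolved (92.2%), and 14 of these were wrong (0.114%). Of 882 resolved genes of inferred length, 3 were wrong. The simulated reads were drawn around the recovered reads, with a log spread of 0.2 and counting noise. A gene misread in the real data was therefore simulated as misread, so these rates do not measure such errors. The limma fit was tested on simulated data for the same comparison with 10156 genes, of which 200 were changed. It recovered 28.4% of genes changed 2-fold, 86.6% of those changed 4-fold and 97.0% of those changed 8-fold, with 14 false calls beside 141 right ones and 0 calls in the wrong direction. In this simulation noise was independent between genes, its spread was capped, and no decimal mark was lost. The real fit called 6243 genes, so these rates need not hold there.

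The recovered reads gave 30186875 to 31001697 assigned reads per KRAS-negative/low library and 34948095 to 38935288 per KRAS-positive library, unresolved genes at their most probable reading included. The library sizes by which the deposited FPKM had been divided, fitted to the values, were 8914123 to 16361573 against 88071658 to 109117415. They followed the median ratio of genes between libraries, so the deposited FPKM were scaled to the median gene and not to all reads. Fold changes on this scale are relative to the median gene, and rescaling every library to a common total (TPM) raised the median gene by 3.27 on the log2 scale.

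The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) with the group as the only term, 2-sided, over genes with a mean FPKM of at least 1 and Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are KRAS-positive minus KRAS-negative/low on that scale, which understates the change of genes near or below 1 FPKM. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 of 29 lists with at least 3 tested members. A camera run with an estimated correlation and fry were alternatives. With 3 libraries against 3, the smallest exact permutation p is 0.1. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Shares of assigned reads count every member of a list at its most probable reading. The share over resolved members alone is given for the enzyme, myeloid, injury and metaplasia lists. Replicates differed by far more than sampling noise, with a chi-square per gene of 56.4 to 98.2 between KRAS-negative/low and 141 to 226 between KRAS-positive libraries.

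The gene lists, the test, its alternatives and the rule for named genes were fixed before the data were examined. The 29 lists were RAS family and regulators; RAF-MEK-ERK cascade; ERK targets; receptor tyrosine kinases; PI3K-AKT-mTOR; digestive enzymes; acinar identity; markers of duct, endocrine, myeloid, lymphocyte, fibroblast, endothelial, erythroid, and adipocyte, mesothelial and Schwann cells; metaplasia and progenitor markers; the unfolded protein, immediate early, interferon and antioxidant responses; proliferation; ribosomal proteins; nuclear-encoded oxidative phosphorylation; mitochondrially encoded transcripts; glycolysis; cholesterol synthesis; pancreatic injury; lysosome and autophagy; and p53 targets. Named genes were Kras; the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change that had a gene symbol and moved the same way in each same-numbered pair; up to 4 members of a described list with the smallest p; fixed RAS, ERK and identity genes; and any gene above 5% of summed FPKM in a library. The unnumbered columns share a heading, but no title carries it, so the pair condition was replaced by groups that do not overlap, which meets it under any pairing. How many members were named per list, from 2 to 4, was chosen after a first look at the lists.

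Alternatives fixed before the data were examined were a pseudocount of 0.1 or 0.25, no filter or a mean FPKM of at least 5, TPM, median-of-ratios factors, totals without the digestive enzymes, quantile normalization, robust empirical Bayes, array weights, a block for the replicate number, and leaving out libraries. An alternative for raw counts was not run because the table holds none. The fit of the array weights stopped before reaching its convergence tolerance, so that alternative is approximate. In some fits with fewer than 6 libraries limma moved a sample variance of 0 away from 0, which did not occur in the main fit. Another 8 were chosen after seeing the data. They were a block for the number heading the columns over all 6 libraries, alone or with median-of-ratios factors, a posterior of at least 0.99, all genes at their most probable reading, recovery from the replicate spread alone, no genes of inferred length, and limma-voom on the recovered reads with the fitted library sizes or with all assigned reads. Amylase, trypsin and elastase genes are families of similar copies, so the split of reads between their members is uncertain.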

Results

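Transcriptomes of sorted pancreatic cells were compared between cells with and without a clear signal of a Citrine-KRAS fusion protein. The labels describe both as acinar cells, the cells that make and secrete digestive enzymes. That identity rests on the labels. Digestive enzymes took 6.22% of assigned reads in KRAS-positive and 80.1% in KRAS-negative/low libraries, and markers of other cell types were higher in the former. KRAS is a small GTPase that passes growth factor signals to the RAF, MEK and ERK kinases. There were 3 libraries of KRAS-positive and 3 of KRAS-negative/low cells. The depth recovered from the deposited FPKM was 34948095 to 38935288 assigned reads per KRAS-positive and 30186875 to 31001697 per KRAS-negative/low library. Reads were spread very differently between genes in the groups, and the deposited values are scaled to the median gene, so higher and lower mean relative to the median gene unless another scale is named.

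The Kras transcript (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239 on the minus strand, GRCm38) was higher in the cells sorted as KRAS-positive. Its level was 4.41 ± 0.0799 FPKM in KRAS-positive and 2.39 ± 0.556 FPKM in KRAS-negative/low libraries (SD, n = 3 each), a ratio of 1.84. The log2 fold change was 0.68 (SE 0.15, limma adjusted p = 0.00514), and all 3 KRAS-positive libraries lay above all 3 others. Between 2036 and 2615 reads per KRAS-positive library and 112 to 192 per KRAS-negative/low library lay behind these values. An exact permutation test gave p = 0.1 (2-sided), the smallest that 3 against 3 libraries allow. The call was lost without both libraries numbered 1659 (log2 fold change 0.60, limma adjusted p = 0.063; range over all alternatives 2.04e-09 to 0.063). After rescaling every library to a common total (TPM), the log2 fold change was 4.10. The sort was on the KRAS fusion protein, so Kras is the gene the groups were chosen by.

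Nras, a RAS paralog, rose 2.83-fold, from 2.81 ± 0.198 to 7.96 ± 0.550 FPKM (limma adjusted p = 0.000156). Hras went the other way relative to the median gene, from 6.73 ± 2.06 to 2.49 ± 0.482 FPKM (limma adjusted p = 0.00245), but was higher in KRAS-positive cells by 2.32 on the log2 TPM scale. Of the 35 tested members of the RAS family and regulators list, 18 rose, 5 fell and 12 did not pass, and adjusted over the list alone 19 rose and 5 fell. All 35 were called higher with TPM, and with totals without the digestive enzymes 29 were higher and 0 lower. Over all 10156 tested genes these scales called 9786 and 6193 higher. The TPM count alone therefore does not set the list apart. The 4 with the smallest p were Rasgrp3 and Rasgrp4, exchange factors that load RAS with GTP, at log2 fold changes of 3.06 and 3.22, and Rasa3 and Rasal2, which belong to the family of RAS GTPase activators, at 2.99 and 1.47. The list was higher than other genes (median log2 fold change 0.42, camera adjusted p = 0.0355), in a call that depends on the settings. It was lost with an estimated correlation (adjusted p = 0.48), on the TPM scale (0.0521), with a mean FPKM of at least 5 (0.0600), without genes of inferred length (0.0524) and without both unnumbered libraries (0.0583). A block over the 4 libraries numbered as in the titles ended it too (0.104, and 0.0597 with median-of-ratios factors). A block by heading over all 6 did not (0.0458 and 0.0443). Markers of myeloid cells, in which Rasgrp4 is also known to be expressed, rose in the same libraries. The myeloid list took 0.00907% of assigned reads in KRAS-negative/low (0.00581% without the unnumbered library) and 2.73% in KRAS-positive libraries.

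In the RAF-MEK-ERK cascade list, 11 of 28 tested members rose, 4 fell and 13 did not pass, with the same counts adjusted over the list alone. Pea15a, an ERK-binding protein, rose 12.7-fold (4.30 ± 1.35 to 54.4 ± 9 FPKM), the scaffold gene Iqgap1 3.82-fold, the scaffold gene Ksr1 5.11-fold and the ERK-activated kinase gene Rps6ka3 2.81-fold (limma adjusted p from 1.91e-05 to 0.000616). Mapk3 was 33.4 ± 0.996 FPKM in KRAS-positive against 21.2 ± 2.87 FPKM in KRAS-negative/low libraries (log2 fold change 0.64, limma adjusted p = 0.0243). Map2k2 fell from 16.2 ± 3.59 to 6.14 ± 0.583 FPKM (limma adjusted p = 0.000992), although it was higher by 2.52 on the log2 TPM scale. Araf, Braf, Raf1, Map2k1 and Mapk1 did not pass, with log2 fold changes of 0.22, 0.26, -0.11, 0.38 and -0.47 and limma adjusted p of 0.312, 0.124, 0.501, 0.102 and 0.0583. As a set the list did not differ from other genes (median 0.29, camera adjusted p = 0.213, and adjusted p = 0.48 with an estimated correlation). All 28 members were called higher on the TPM scale, and with totals without the digestive enzymes 24 were higher and 0 lower. Over all 10156 tested genes those scales called 9786 and 6193 higher. Camera called the list on neither scale (adjusted p = 0.104 and 0.12). The call for Mapk3 was lost when any single KRAS-positive library was left out (limma adjusted p = 0.0862, 0.0598 and 0.0677), without the KRAS-negative/low library 1659 (0.0583) and with the block over the 4 libraries numbered as in the titles (0.0931, and 0.0508 with median-of-ratios factors) or by heading over all 6 (0.0574).

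Transcripts that ERK signalling is known to induce were higher more often than lower. Of 16 tested members of the ERK target list, 9 rose, 1 fell and 6 did not pass, the same as adjusted over the list alone. On the TPM scale all 16 were higher, but so were 9786 of all 10156 tested genes. Dusp6, the ERK phosphatase, rose 6.13-fold from 7.19 ± 3.16 to 44.0 ± 3.74 FPKM (limma adjusted p = 0.000257). The transcription factor gene Etv1 rose from 0.14 ± 0.110 (0.0767 without the unnumbered library) to 2.73 ± 0.263 FPKM. The RAS inhibitor gene Spred1 rose from 2.98 ± 0.646 to 15.2 ± 2.83 FPKM and Phlda1 from 1.03 ± 0.122 to 5.62 ± 1.47 FPKM. Cdc25a, a cell cycle phosphatase, fell from 4.56 ± 0.667 to 0.891 ± 0.157 FPKM and was higher by 1.34 on the log2 TPM scale. Etv5 was 7.49 ± 1.99 against 11.5 ± 1.71 FPKM (limma adjusted p = 0.0485), a call lost without the unnumbered KRAS-negative/low library (limma adjusted p = 0.0857), without KRAS-negative/low 1659 (0.187), without KRAS-positive 1551 (0.136), without KRAS-positive 1659 (0.139) and with the block by heading (0.0553). Spry2 did not pass (5.04 ± 1.57 against 6.41 ± 2.30 FPKM, limma adjusted p = 0.37), and Etv4 was too low to be tested (0.631 ± 0.306 against 0.118 ± 0.0176 FPKM). The list was higher than other genes (median 0.79, camera adjusted p = 0.0305). That call was lost in 11 alternatives: with an estimated correlation (adjusted p = 0.48), on the TPM scale (0.229), with totals without the digestive enzymes (0.0865), with array weights (0.0582), with the block over 4 libraries (0.0718, but 0.0246 over all 6) and with a mean FPKM of at least 5 (0.0525). The others were all genes at their most probable reading (0.0667), no genes of inferred length (0.0524), limma-voom on all assigned reads (0.191), leaving out the KRAS-positive library 1659 (0.0686) and leaving out both libraries 1659 (0.0527). The immediate early list, which shares Egr1 with it and contains genes induced by tissue dissociation, took 2.80% of assigned reads in KRAS-positive and 0.17% in KRAS-negative/low libraries.

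**Figure D1:**
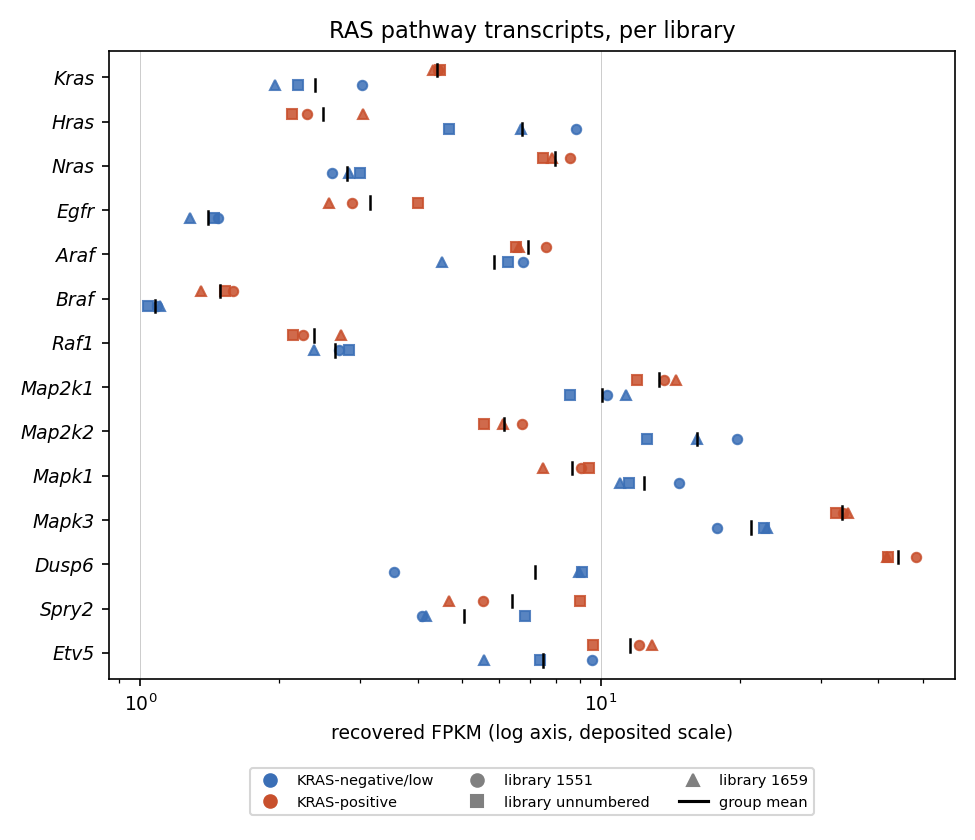
Recovered FPKM of 14 RAS pathway transcripts on a log axis for the 3 KRAS-negative/low (blue) and 3 KRAS-positive (orange) libraries, with marker shapes for the library number and a bar for each group mean. Kras lies between 1.96 and 3.02 FPKM in KRAS-negative/low and between 4.32 and 4.48 FPKM in KRAS-positive libraries; Hras and Map2k2, lower here, are higher on the TPM scale.

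Among receptor tyrosine kinases, ligands and adaptors, 9 of 23 tested members rose, 6 fell and 8 did not pass (the same counts adjusted over the list alone), whereas on the TPM scale 22 were higher and 1 lower. Egfr, the epidermal growth factor receptor, rose from 1.40 ± 0.104 to 3.16 ± 0.759 FPKM (limma adjusted p = 0.00334) and the adaptor and ubiquitin ligase gene Cbl from 1.78 ± 0.439 to 10.3 ± 1.55 FPKM. Egf, a ligand of Egfr, fell from 9.13 ± 3.81 to 0.203 ± 0.0524 FPKM. The list did not differ from other genes (median -0.00, camera adjusted p = 0.619, test direction up). In the PI3K-AKT-mTOR list 12 of 25 rose, 5 fell and 8 did not pass, again with the same counts adjusted over the list alone (median 0.42, camera adjusted p = 0.193). On the TPM scale all 25 were higher, as were 9786 of all 10156 tested genes, and the list was not called (camera adjusted p = 0.171). Pik3cg and Inpp5d, a kinase and a phosphatase of phosphoinositides known from blood cells, rose by 2.88 and 3.24 on the log2 scale.

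Digestive enzyme transcripts were far lower in KRAS-positive cells. Chymotrypsinogen Ctrb1 fell from 430762 ± 153851 to 4614 ± 2408 FPKM, pancreatic lipase Pnlip from 166520 ± 59616 to 1650 ± 532 FPKM and carboxypeptidase Cpa1 from 88444 ± 25832 to 900 ± 388 FPKM, ratios of 93.4, 101 and 98.2. All 23 tested enzymes fell, adjusted over all genes or over the list alone, with a median log2 fold change of -6.63 (camera adjusted p = 4.76e-13, and adjusted p = 0.48 with an estimated correlation). The list took 80.1% ± 2.43 of assigned reads in KRAS-negative/low and 6.22% ± 2.62 in KRAS-positive libraries (SD, n = 3 each), or 72.2% ± 1.80 and 5.58% ± 2.28 over resolved members alone. On the TPM scale all 23 were still lower, with a median of -2.60. The 12 called genes with the most negative log2 fold change were Spink1 (-7.16), Amy2a3, Clps, Amy2a1, Klk1, Gp2, Reg1, Pnliprp1, Pnliprp2, Rnase1, Amy2b and Cpa1 (-6.65), which are secreted or granule proteins of acinar cells. Genes above 5% of summed FPKM in a library were Ctrb1, Pnlip, Try4, Prss2 and Try5, and Try5 was not tested because its decimal mark stayed open. Quantile normalization, which forces one distribution on all libraries, brought the log2 fold changes of Pnlip, Prss2 and Try4 to -0.26, -0.22 and -0.21 and that of Ctrb1 to 0, and ended all 4 calls (limma adjusted p = 0.157, 0.445, 0.353 and 1). Dropping the filter on low genes left their log2 fold changes as they were, at -6.63, -6.53, -6.63 and -6.59, but over the 26160 genes then tested none of the 4 was called (limma adjusted p = 0.281, 0.216, 0.252 and 0.603). The number of tests alone does not explain this, since their unadjusted limma p in the main fit were 3.14e-07 to 9.35e-07. What else changed in the fit was not tested.

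Acinar transcription factors and receptors were lower too, relative to the median gene. Of 23 tested members of the acinar identity list, 19 fell, 1 rose and 3 did not pass, the same as adjusted over the list alone (median -3.20, camera adjusted p = 9.59e-08, and adjusted p = 0.48 with an estimated correlation). Bhlha15, the factor also called MIST1 that sets up the secretory apparatus, fell from 58.8 ± 17 to 1.05 ± 0.443 FPKM. The water channel Aqp12 fell from 421 ± 132 to 3.44 ± 1.30 FPKM and the endoplasmic reticulum chaperone Erp27 from 131 ± 45.3 to 1.34 ± 0.635 FPKM (limma adjusted p from 3.23e-06 to 5.06e-06). On the TPM scale 10 members were higher and 10 lower, with a median of 0.33. With limma-voom on all assigned reads 6 were higher and 11 lower, with a median of -0.87. Ptf1a and Nr5a2, core acinar factors, were not tested because their decimal marks stayed open (posterior 0.885 and 0.939); their most probable readings were 22.8 ± 6.60 against 0.191 ± 0.228 FPKM (0.0646 without the unnumbered KRAS-positive library) and 12.1 ± 1.55 against 1.37 ± 0.406 FPKM.

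The unfolded protein response list, which serves secretory cells, fell in 15 of 22 tested members, rose in 1 and did not pass in 6, the same as adjusted over the list alone (median -1.89, camera adjusted p = 0.000106, and adjusted p = 0.515 with an estimated correlation). Derl3 and Chac1 fell from 97.5 ± 65.1 to 1.57 ± 0.595 FPKM and from 52.9 ± 25.5 to 1.71 ± 1.40 FPKM. Without KRAS-negative/low 1551 the first mean of Derl3 was 60.1 FPKM, and without KRAS-positive 1659 the second of Chac1 was 0.917 FPKM. Cytosolic ribosomal proteins fell in 63 of 64 tested members and nuclear-encoded oxidative phosphorylation genes in 65 of 69, with none higher in either, adjusted over all genes or over the list alone (medians -2.56 and -1.76, camera adjusted p = 7.04e-15 and 1.36e-15, and adjusted p = 0.48 for both with an estimated correlation). Rpl41 and Rpl38 had log2 fold changes of -3.86 and -3.53, and Uqcrq and Uqcr11 of -3.28 and -2.70. All 4 were above 0 on the TPM scale. With limma-voom on all assigned reads Rpl41, Rpl38 and Uqcrq were lower, at -1.05, -0.76 and -0.62 (adjusted p = 0.000785, 0.0111 and 0.023), and Uqcr11 was not called. These directions hold relative to the median gene. On the TPM scale 18 of the 22 unfolded protein response members, 62 of the 64 ribosomal and all 69 oxidative phosphorylation genes were higher, with medians of 1.64, 1.45 and 2.03 against 3.27 for the median gene. The 2 scales by all reads differ, since limma-voom on all assigned reads called 10, 20 and 50 of them higher and 3, 2 and 1 lower, with medians of 0.49, 0.24 and 0.93.

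Myeloid transcripts had the highest median of the 28 lists with a set test. Of the macrophage and myeloid list, all 16 tested members rose, also adjusted over the list alone, while 9 others stayed unresolved (median 4.76, camera adjusted p = 1.73e-10, and adjusted p = 0.48 with an estimated correlation). The complement genes C1qa and C1qb, made by macrophages, went from 1.55 ± 0.658 to 791 ± 127 FPKM and from 1.17 ± 0.714 to 470 ± 114 FPKM. The receptor gene Csf1r, the surface marker gene Adgre1 (F4/80) and Cd68 went from 1.72 ± 0.332 to 236 ± 83.1, from 0.372 ± 0.0804 to 91.9 ± 22.9 and from 1.23 ± 0.183 to 109 ± 22.9 FPKM. Ptprc, the pan-leukocyte marker CD45, went from 0.791 ± 0.545 (0.506 without the unnumbered library) to 10.4 ± 4.47 FPKM. The 12 called genes with the largest log2 fold change were C1qa (8.30), C1qb, Cbr2, Pf4, Stab1, Lyve1, F13a1, Dab2, Fcna, Csf1r, Wfdc17 and Ccl2 (6.19), with limma adjusted p of 6.01e-06 or less. Many of them, such as Stab1, Lyve1, F13a1, Pf4 and Cbr2, are known from tissue-resident macrophages. The list took 2.73% ± 0.691 of assigned reads in KRAS-positive and 0.00907% ± 0.00568 in KRAS-negative/low libraries (SD, n = 3 each), or 1.12% ± 0.211 and 0.00263% ± 0.00203 over resolved members alone. Without the unnumbered library the KRAS-negative/low shares were 0.00581% and 0.00147%.

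Markers of other stromal cells rose in the same libraries. Of the fibroblast and stellate cell list, 14 of 15 tested members rose and 1 did not pass (median 3.36, camera adjusted p = 1.26e-05), and of the endothelial list all 14 rose (median 2.95, camera adjusted p = 1.04e-06), with the same counts adjusted over each list alone and adjusted p = 0.48 for both with an estimated correlation. Collagen genes Col1a1 and Col1a2 went from 0.863 ± 0.585 to 47.8 ± 38.0 FPKM and from 0.449 ± 0.299 to 26.7 ± 19.3 FPKM (26 and 15.8 without the unnumbered KRAS-positive library), and Serpinf1 from 0.422 ± 0.201 to 14.7 ± 8.08 FPKM. The endothelial receptor genes Tek and Tie1 reached 10.2 ± 5.38 and 9.70 ± 3.36 FPKM, Ptprb 10.2 ± 5.16 FPKM and Pecam1 19 ± 8.46 FPKM, from 0.264 ± 0.106, 0.43 ± 0.365, 0.317 ± 0.160 and 0.978 ± 0.847 FPKM. Without the unnumbered KRAS-negative/low library Tie1 was at 0.223 and Pecam1 at 0.505 FPKM in that group. The fibroblast list took 2.26% of assigned reads in the unnumbered KRAS-positive library, 0.83% in 1551 and 0.733% in 1659. Against the TPM background the fibroblast list was not called (camera adjusted p = 0.229), with all 15 members higher. With limma-voom on all assigned reads neither list was called (0.191 for fibroblast and 0.0895 for endothelial markers).

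Duct markers fell relative to the median gene in 16 of 22 tested members, rose in 1 and did not pass in 5, the same as adjusted over the list alone (median -1.23, camera adjusted p = 0.000789, and adjusted p = 0.515 with an estimated correlation). With TPM 19 were higher and 1 lower, with a median of 2.01. With limma-voom on all assigned reads the counts were 12 and 2, with a median of 1.16. Krt19 and Sox9 fell from 44.9 ± 11.2 to 10.8 ± 4.62 FPKM and from 27.2 ± 14.3 to 7.39 ± 2.89 FPKM (limma adjusted p = 0.000917 and 0.0145), and on the log2 TPM scale were higher by 1.86 and 2.15. With limma-voom on all assigned reads neither was called (0.70 and 1.07, adjusted p = 0.0893 and 0.0743). On the deposited scale the call for Sox9 was lost without the KRAS-positive library 1551 (limma adjusted p = 0.0534). Tff2, an abundant secreted peptide, fell from 4746 ± 1496 to 50.8 ± 23.7 FPKM, Muc1 from 105 ± 22.6 to 6.06 ± 2.85 FPKM and Cldn7 from 23.7 ± 3.22 to 3.78 ± 0.965 FPKM, of which Cldn7 was higher by 1.29 on the log2 TPM scale and Muc1 was not called there (-0.17, limma adjusted p = 0.596). With limma-voom on all assigned reads Muc1 was lower (-1.38, adjusted p = 0.00128) and Cldn7 was not called (0.15, adjusted p = 0.599). Aqp1, a water channel also found in endothelium, rose from 1.30 ± 0.563 to 20.5 ± 8.54 FPKM. The list's share of assigned reads was 0.324% ± 0.103 in KRAS-negative/low and 0.276% ± 0.05 in KRAS-positive libraries. Tff2 weighs on this difference, with 29264 to 32696 reads per KRAS-negative/low and 2047 to 4009 per KRAS-positive library. It was lower on the log2 TPM scale too (-2.55, limma adjusted p = 1.14e-06).

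Endocrine markers went both ways, with 5 of 7 tested members higher and 2 lower, also adjusted over the list alone (median 1.42, camera adjusted p = 0.377), while 9 members stayed unresolved. With TPM 5 were higher and 0 lower, and with limma-voom on all assigned reads 5 and 2. On both of these scales the list was called below other genes (camera adjusted p = 0.0473 and 0.0232), against a test direction of up on the deposited scale. Mafb, a transcription factor that macrophages express as well, rose from 0.306 ± 0.193 to 79.2 ± 27.4 FPKM. Ttr and Pcsk1 fell from 116 ± 38.1 to 5.34 ± 1.54 FPKM and from 3.17 ± 1.31 to 0.115 ± 0.0717 FPKM (0.0743 without the unnumbered KRAS-positive library). Neither was called with TPM (limma adjusted p = 0.205 and 0.316). With limma-voom on all assigned reads both were lower (-1.62 and -2.00, adjusted p = 0.000282 and 0.00114). Ins2 was not tested because its decimal mark stayed open. Of metaplasia and progenitor markers 5 of 13 tested rose, 7 fell and 1 did not pass, the same as adjusted over the list alone (median -0.86, mean 0.04, camera adjusted p = 0.619, test direction down). Another 7 of the 28 members stayed unresolved. This list took 0.067% of assigned reads in KRAS-negative/low and 0.372% in KRAS-positive libraries, or 0.0573% and 0.165% over resolved members alone. All 13 tested members were higher on the TPM scale, with a median of 2.62 against 3.27 for the median gene. With limma-voom on all assigned reads 8 were higher and 0 lower, with a median of 1.73. Anxa1 rose from 1.32 ± 0.559 to 35.3 ± 9.67 FPKM, whereas Cd24a fell from 113 ± 31.3 to 12.4 ± 0.959 FPKM and Pdx1 from 3.60 ± 0.467 to 0.663 ± 0.176 FPKM, both of which were higher on the log2 TPM scale (0.87 and 1.17) but not called with limma-voom on all assigned reads (log2 fold change -0.32 and 0.36, adjusted p = 0.184 and 0.438).

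**Figure D2:**
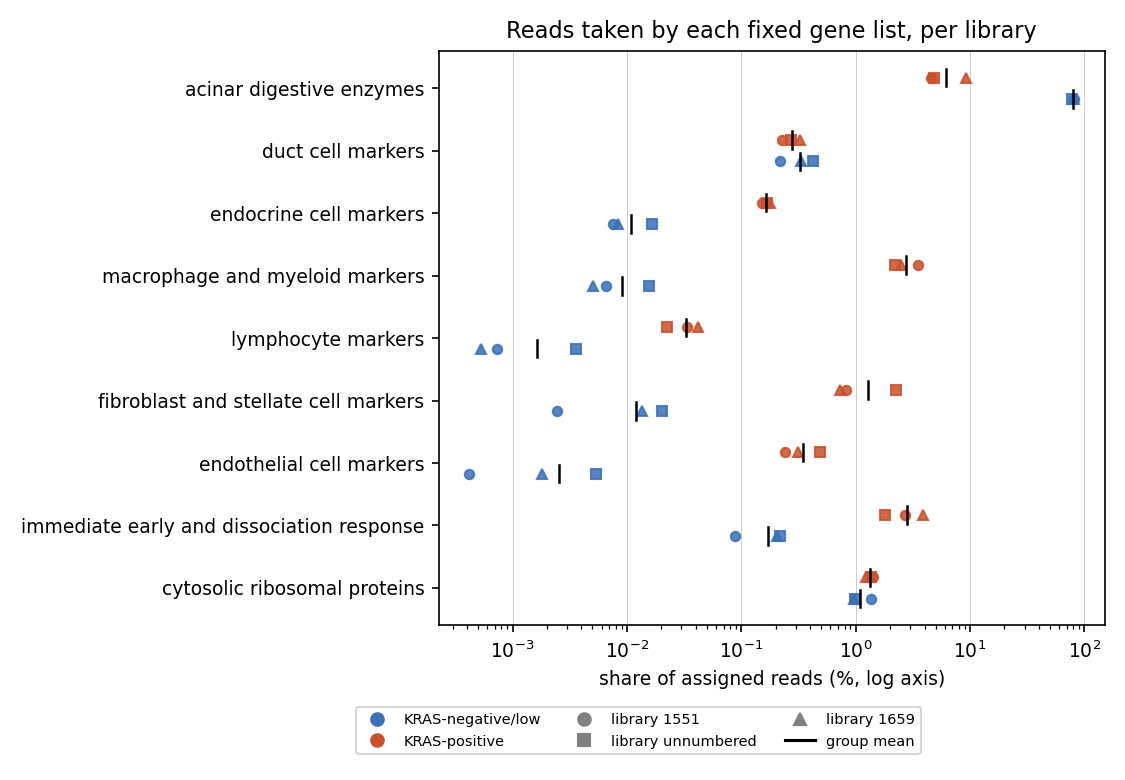
Share of assigned reads (percent, log axis) taken by 9 gene lists in each library, with colours for the groups, marker shapes for the library number and a bar for each group mean. Digestive enzymes take 77.3% to 81.9% in KRAS-negative/low and 4.6% to 9.24% in KRAS-positive libraries, and the myeloid, fibroblast and endothelial shares do not overlap between the groups.

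Immediate early genes, which tissue dissociation is known to induce, rose in 9 of 15 tested members and did not pass in 6, the same as adjusted over the list alone (median 1.15, camera adjusted p = 0.00644, and adjusted p = 0.48 with an estimated correlation). A further 9 members stayed unresolved. Zfp36 went from 6.61 ± 2.45 to 295 ± 134 FPKM, Klf2 from 11 ± 1.70 to 165 ± 75.1 FPKM and the heat shock gene Hspa1b from 0.706 ± 0.492 (0.427 without the unnumbered library) to 16 ± 8.16 FPKM. Interferon response genes rose in 14 of 15, and in all 15 adjusted over the list alone (median 1.30, camera adjusted p = 1.79e-05, and adjusted p = 0.48 with an estimated correlation), with Oas1a from 0.0937 ± 0.084 (0.0595 without the unnumbered library) to 6.15 ± 1.25 FPKM and Oasl2 from 0.143 ± 0.0263 to 3.08 ± 0.636 FPKM. Pancreatic injury and inflammation genes rose in 5 of 6 tested members, and in all 6 adjusted over the list alone (median 1.91, camera adjusted p = 0.00165, and adjusted p = 0.48 with an estimated correlation). These 6 are a small part of the list, of which 12 members stayed unresolved. Over all members its share of assigned reads was 0.174% ± 0.064 in KRAS-negative/low and 0.32% ± 0.0912 in KRAS-positive libraries, but over resolved members alone 0.00101% ± 0.000356 and 0.0918% ± 0.0442. The risen members include the monocyte chemokines Ccl2 and Ccl7, at 155 ± 81.4 and 100 ± 65.1 FPKM in KRAS-positive libraries (62.6 for Ccl7 without 1551), and the adhesion molecule Icam1, from 0.866 ± 0.193 to 6.29 ± 1.44 FPKM. These changes came in the same libraries as the rise of the myeloid, fibroblast and endothelial markers. On the TPM scale none of these 3 lists was called above the other genes (camera adjusted p = 0.133, 0.114 and 0.0994). Of the proliferation list 6 of 8 tested members rose and 2 did not pass, the same as adjusted over the list alone (median 0.70, camera adjusted p = 0.055). Mki67 was too low to be tested (0.174 ± 0.121 against 1.29 ± 0.985 FPKM, or 0.112 without the unnumbered KRAS-negative/low library and 0.846 without KRAS-positive 1551).

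Over all 10156 tested genes, 3101 were higher and 3142 lower in KRAS-positive cells (limma adjusted p below the threshold of 0.05), so that 49.7% of the called genes were higher. This split is set by the scale: with TPM 9786 were higher and 110 lower (98.9% higher), and with totals that leave out the digestive enzymes 6193 were higher and 1114 lower (84.8% higher), the median gene moving by 3.27 and 1.10 on the log2 scale. The groups did not overlap for 7146 genes (70.4%), where chance gives 10% for 3 against 3. The first principal component held 88.9% of the variance. Pearson correlations across genes, which are not independent replicates, were 0.951 to 0.976 within KRAS-negative/low, 0.934 to 0.958 within KRAS-positive and 0.478 to 0.589 between the groups. The recovery of decimal marks used the group labels, so the share of genes without overlap and the correlations within groups may be too high. Camera called 14 of 28 lists; with an estimated correlation it called 0 of 28, also 0 at an unadjusted p under 0.05 (smallest 0.0503), and fry, which asks only whether a list's genes move one way, called 19.

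**Figure D3:**
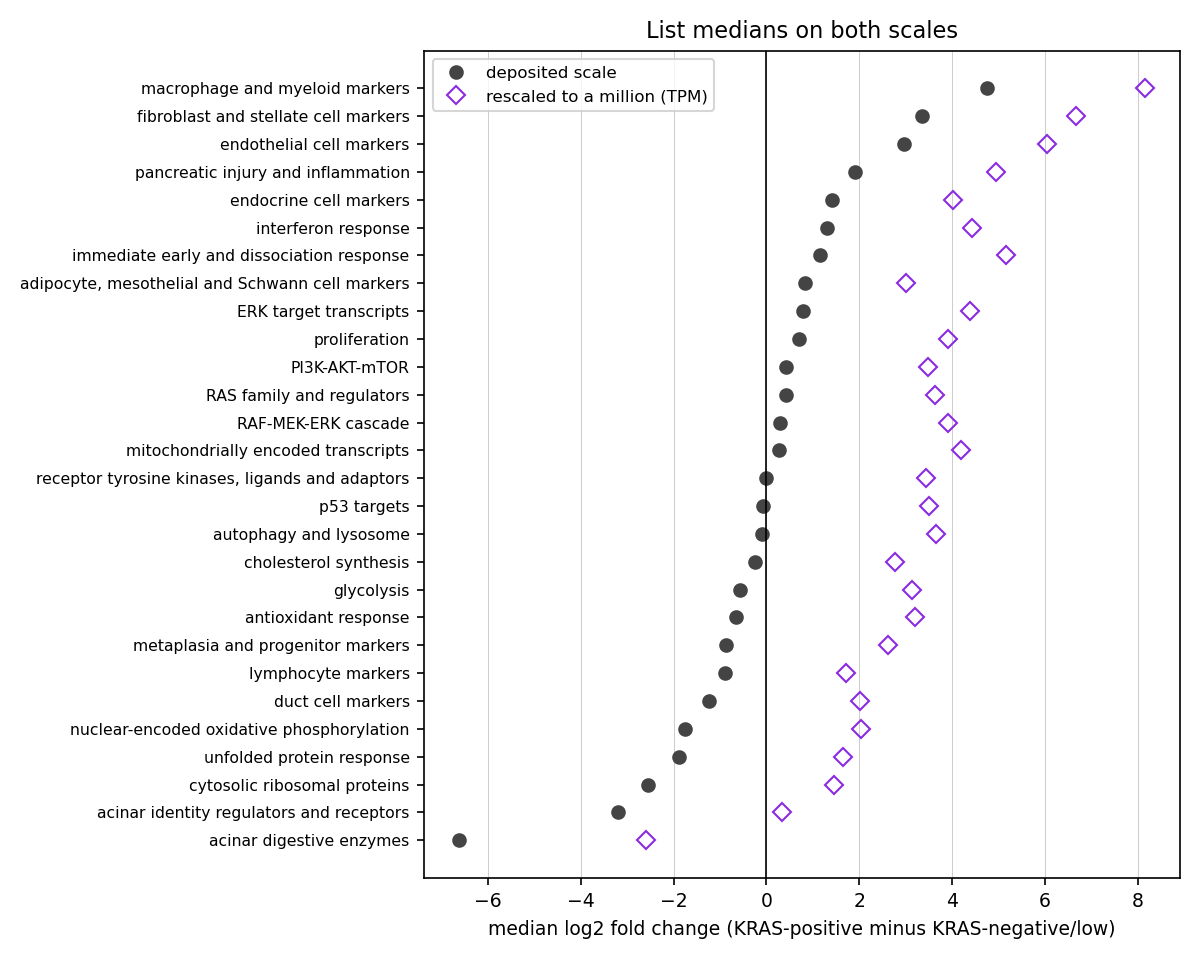
Median log2 fold change (KRAS-positive minus KRAS-negative/low) of the tested members of 28 gene lists on the deposited scale (filled circles) and on the TPM scale (open diamonds). The digestive enzymes are the only list below 0 on both scales (-6.63 and -2.60), and the myeloid list is highest on both (4.76 and 8.16).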

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

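The tests of recovery settings, the limma-voom fits and the block by column heading were chosen after seeing the data; the other alternatives were fixed before. Of 97 other named genes tested, 67 kept their direction and their side of the threshold in every alternative run for them, and 15 reversed in at least 1. The scale had the widest effect, since the deposited values are relative to the median gene. Genes higher and lower in KRAS-positive cells, 3101 and 3142 as reported, became 9786 and 110 with TPM, 6193 and 1114 with totals without the digestive enzymes, and 9064 and 251 with limma-voom on all assigned reads. With a mean FPKM of at least 5 they were 1027 and 1571 of 3625 tested genes, and with array weights, whose estimation stopped before convergence, 4044 and 4000. Leaving out 1 library gave 2570 to 3022 higher and 2536 to 3150 lower, and leaving out both libraries with the same heading gave 2255 to 2722 and 2302 to 2853.

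On the TPM scale the log2 fold changes turned positive for Hras (2.32), Map2k2 (2.52), Mapk1 (3.32), Raf1 (3.13), Cdc25a (1.34), Krt19 (1.86), Sox9 (2.15), Cldn7 (1.29), Cd24a (0.87), Pdx1 (1.17), Igkc (1.95), Uqcr11 (1.21), Uqcrq (0.58), Rpl38 (0.44) and Rpl41 (0.15). Rpl38 and Rpl41 were not called there (limma adjusted p = 0.113 and 0.548). With limma-voom on all assigned reads they were positive for Hras (1.41), Map2k2 (1.45), Mapk1 (2.30), Raf1 (2.66), Cdc25a (0.46), Krt19 (0.70), Sox9 (1.07), Cldn7 (0.15), Pdx1 (0.36), Igkc (1.04) and Uqcr11 (0.016), and negative for Cd24a (-0.32), Uqcrq (-0.62), Rpl38 (-0.76) and Rpl41 (-1.05). With totals without the digestive enzymes Mapk1 (0.64) and Raf1 (0.95) were positive. The changes of sign follow from the upward shift that the rescaling makes. Quantile normalization took the call from 4 named genes and dropping the filter from 9, and the cause was not tested.

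Kras kept its direction in all 28 alternatives (log2 fold change 0.59 to 4.10) and its call in 27. TPM says nothing here, since it raised all 10156 tested genes. Totals without the digestive enzymes and limma-voom on all assigned reads say little, since they raised the median gene by 1.10 and 2.81. Without both libraries numbered 1659 it was 0.60 (adjusted p = 0.063), with fewer libraries; other libraries left out gave 0.59 to 0.81. The RAS family and regulators list, at camera adjusted p = 0.0355, lost its call with a mean FPKM of at least 5 (0.0600), TPM (0.0521), no genes of inferred length (0.0524) and an estimated correlation (0.480); libraries left out gave 0.0282 to 0.0583, the highest without both unnumbered ones. The ERK target transcripts list, at 0.0305, lost its call with a mean FPKM of at least 5 (0.0525), TPM (0.229), totals without enzymes (0.0865), array weights (0.0582), all genes at their most probable reading (0.0667), no genes of inferred length (0.0524), limma-voom on all assigned reads (0.191) and an estimated correlation (0.480). Libraries left out gave 0.0147 to 0.0686. The RAF-MEK-ERK cascade list, not called at 0.213, passed with limma-voom on all assigned reads (0.0417) and with fry (0.000948), which makes no comparison with other genes; leaving out libraries gave 0.167 to 0.263. Camera with an estimated correlation called 0 of 28 lists, and 0 at an unadjusted p under 0.05, where fry called 19. For each call lost or gained the cause was not tested.

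The planned replicate block used the 4 libraries whose number is in the titles. The libraries share only a number: deviations from the group means correlated at 0.130 for 1551, 0.147 for 1659 and 0.0743 for the unnumbered pair, and at -0.171 to -0.0176 between headings. All 6 libraries went best with their own heading. Deviations cancel out within a group, so these matches are not independent, and their rate by chance was not computed. They are no more than a hint. With a block by heading over all 6 libraries 3044 genes were higher and 3181 lower, and with median-of-ratios factors as well 3172 and 3133. The RAS family and regulators list stayed called (camera adjusted p = 0.0458 and 0.0443), as did the ERK target transcripts list (0.0246 and 0.0240). Etv5 and Mapk3 lost their call with the block by heading alone (limma adjusted p = 0.0553 and 0.0574). With the block over 4 libraries 2961 genes were higher and 3218 lower, and with median-of-ratios factors as well 2948 and 2956. The RAS family and regulators list had camera adjusted p = 0.104 and 0.0597 over these 4 libraries, and the ERK target transcripts list 0.0718 with the block alone. Of the named genes 1, Mapk3, lost its call in both fits over 4 libraries (log2 fold change 0.72 and 0.77, limma adjusted p = 0.0931 and 0.0508). Raf1, not called in either, had a log2 fold change of 0.019 with that block and median-of-ratios factors (limma adjusted p = 0.939), against -0.11 without them.

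The recovery of decimal marks limits single genes more than counts. With a posterior of at least 0.99, 2808 genes were higher and 2891 lower, and with every gene at its most probable reading 3274 and 3305. In the data simulated around the recovered reads, 14.4% of the 1041 unresolved genes were wrong at their most probable reading. Depth limits the low end of the KRAS-negative/low group, where C1qa rested on 8 to 37 and Fcna on 0 to 1 reads per library.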

Other observations

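The tests of explanations in this part were chosen after the results they weigh were seen, except that of other splits and that of Kras after rescaling. Other gene groups showed smaller or mixed differences relative to the median gene. Of 12 tested mitochondrially encoded transcripts 1 rose and 11 did not pass, and 0 were called adjusted over the list alone (median 0.27, camera adjusted p = 0.403), and the list took 1.60% ± 0.115 of assigned reads in KRAS-positive and 0.228% ± 0.0878 in KRAS-negative/low libraries. With quantile normalization this list was called above other genes (median 1.80, camera adjusted p = 0.0013). Of 18 glycolysis genes 4 rose and 9 fell, or 5 and 10 adjusted over the list alone (median -0.57, camera adjusted p = 0.388). Of 19 cholesterol synthesis genes 3 rose and 5 fell, or 0 and 2 adjusted over the list alone (median -0.24, adjusted p = 0.388). Of 18 antioxidant genes 4 rose and 9 fell, also adjusted over the list alone (median -0.65, adjusted p = 0.237). Of 16 p53 targets 4 rose and 5 fell, or 3 and 5 adjusted over the list alone (median -0.08, mean 0.01, adjusted p = 0.859). Of 27 lysosome and autophagy genes 10 rose and 6 fell, also adjusted over the list alone (median -0.10, mean 0.15, adjusted p = 0.619, test direction up), and with limma-voom on all assigned reads the list was called above other genes (camera adjusted p = 0.0335). On the TPM scale the median of each of these lists was above 0, between 2.76 and 4.18, where the median gene lay at 3.27.

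Lymphocyte transcripts were scarce. The list took 0.00162% of assigned reads in KRAS-negative/low (0.000628% without the unnumbered library) and 0.0326% in KRAS-positive libraries. Of 4 tested members 1 rose and 1 fell, also adjusted over the list alone (median -0.89, mean 0.21, camera adjusted p = 0.905, test direction down). On the TPM scale 3 were higher and 0 lower, yet the list was called below other genes (camera adjusted p = 0.0291). Ighm rose from 2.74 ± 1.56 to 56.5 ± 25.9 FPKM, whereas Igkc fell from 6.92 ± 2.71 to 2.29 ± 1.41 FPKM (limma adjusted p = 0.0187) and was higher by 1.95 on the log2 TPM scale. The call for Igkc was lost without KRAS-negative/low 1551 (limma adjusted p = 0.0711), the unnumbered KRAS-negative/low library (0.0539) or KRAS-positive 1659 (0.0512). Of adipocyte, mesothelial and Schwann cell markers 3 were tested and 1 fell, also adjusted over the list alone (median 0.84, camera adjusted p = 0.905, test direction down). Of erythroid markers 1 was tested and did not pass, so the list had no set test.

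Explanations are hypotheses. Those for the enzyme and myeloid transcripts were tested on the share of all assigned reads, that for Kras on TPM, and the splits on the deposited scale.

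Digestive enzyme transcripts were lower in KRAS-positive cells. Scaling to the median gene is argued against as the whole cause, since the median log2 ratio of read shares over 23 enzymes was -3.7361 and the summed shares lay 68.1 percentage points apart, against a spread of 4.64 within groups. Dilution of acinar RNA by RNA of other cells, with no change within acinar cells, stays open: over 8 regulators and receptors, picked from the acinar identity list after the results were seen, the median was -3.19, or 0.549 above that of the enzymes, but over all 23 tested members of that list it was -0.71, or 3.03 above. Other cells are also known to express some members of the full list, so neither value decides it. A biological difference between acinar cells with much and little KRAS stays open and was not tested apart from the mixture.

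Myeloid, fibroblast and endothelial transcripts were higher in KRAS-positive cells. A lower share of acinar RNA that raises all other cell types alike is argued against, because list medians of the log2 read-share ratio ranged over 7.6255, from 0.98 for duct to 8.60 for myeloid markers. Fibroblast and endothelial markers lay nearer the myeloid list, at 7.83 and 7.02, and endocrine markers at 5.78 over 7 genes. The argument thus rests on the duct list and on lymphocyte markers (1.04 over 4 genes). RNA of myeloid cells in the sorted fraction stays open as a candidate source: over all 26 genes of the myeloid list, 9 of them unresolved and taken at their most probable reading, the median log2 ratio was 7.7711 and the lowest 2.71. The labels describe the sorted cells as acinar and name no gate against leukocytes. Whether such cells carried the Citrine-KRAS signal or entered the gate in another way, such as by autofluorescence, was not tested.

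RAS, RAF-MEK-ERK and ERK target transcripts differed between the groups. The log2 fold change of Kras was 0.68 on the deposited scale and 4.0994 after rescaling to TPM. That rescaling raised all 10156 tested genes, so a positive value could not change sign, and TPM cannot decide whether scaling sets the direction. Kras was also higher with quantile normalization (0.62, limma adjusted p = 0.00493). With totals without the digestive enzymes it was higher by 1.97 (limma adjusted p = 6.89e-05), but that scale moved the median gene up by 1.10. Quantile normalization moved the median gene by only -0.06 on the log2 scale. No scale tried moved the median gene down far enough to reverse Kras, so none decides the direction. Different cell types in the groups and the KRAS level cannot be told apart for these lists, because the enzyme share of reads separated the groups by 68.0731 percentage points without overlap. The same counts could therefore come from acinar cells with more KRAS or from a mixture with myeloid and stromal cells. Single-cell profiles of both gates would separate them.

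Of the 10 splits of the 6 libraries into 3 and 3, 1 gave at least as many called genes as the real split, the real one itself. It called 6243 genes by limma and the highest of the others 0, or 6678 and 128 at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05. The decimal marks were recovered with the real groups as input, and every other split mixes both groups. Low counts in the other splits were thus set in advance, and nothing about chance is concluded from them.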
